A study of Mus musculus with 6 samples.

How the data were processed

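Condylar cartilage dissected under a microscope gave 3 control and 3 mutant libraries, per the labels, and each library was grouped by its label. Total RNA was isolated with the miRNeasy Mini Kit, full-length cDNA was made with the SMART-Seq HT Kit and libraries were made with the Nextera DNA kit, per the labels' protocols. Such libraries do not keep the strand of the transcript. The series description says that mutant samples were checked by Ihh, Cre and Tomato expression, and Cre and Tomato were not analysed here. Age, sex, the part of Ihh that was deleted and the gene annotation are not given in the sources used here.

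The deposited tables, 1 per library, gave 24346 gene symbols with values that the authors had made as FPKM. The headers name no unit. FPKM was inferred from values that are not whole and never below 0, from column sums that differ between libraries (581072 to 738395) and from Cufflinks in the processing notes. TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 with the build mm10 were used, per the submitters' processing notes, which give neither their order nor their settings. Whether the authors scaled libraries beyond FPKM is not given in the sources used here.

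The groups, the comparison, the tests, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. The plan held a test for counts and a test for normalized values, and the latter was used. Genes with at least 1 FPKM in at least 3 libraries (18715 genes) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as limma-trend with robust empirical Bayes moderation and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A log2 fold change is given with its standard error, and FPKM values are means with standard deviations over 3 libraries. A fold of means is the ratio of mean FPKM.

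Of 29 gene lists of pathways, cell types and signs of handling, 27 with at least 5 tested genes were compared with all other genes by camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Sex-linked and mitochondrially encoded genes were only described. The lists called with the preset correlation numbered 11. The genes of each list were also adjusted over the list alone.

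The rule for named genes took Ihh, the measured members of the hedgehog response list, and the 10 largest called changes in each direction. For the last, a mean of at least 5 FPKM and full separation of the groups were required, and predicted or unnamed genes were left out. It also took up to 4 members of each list with the smallest p. Not every gene that the rule took is reported here. Other genes are said to have been chosen after their values were seen. Of the 232 called genes, 4 were predicted or unnamed and 2 were small RNA genes.

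Numbers of fragments were recovered for Ihh, Ptch1 and Foxd2 as the smallest whole numbers that fit the 6 values at 1 scaling total per library, within 0.1 of a fragment. The largest deviation for Ihh was 0.002. The totals are relative to control 1, so the absolute depth stayed unknown. Ratios of these numbers carry exact 95% intervals that cover counting error only. The search ended at 40 fragments in the library with the most. Gli1 and Hhip gave no solution up to that number, and larger numbers were not searched. Olfactory receptor genes were chosen as a measure of background after the data were seen. Gene coordinates and overlaps were taken from GENCODE release M21.

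The procedure was tested on simulated data with 18715 genes, of which 100 changed by a log2 fold change of 1 and 100 by 2. It recovered 16% of the former and 69% of the latter, with 3 false calls among 88, and made 0 calls where nothing changed. Changes of 1 log2 unit were thus mostly missed at 3 libraries per group. The changed genes were drawn from those with a mean of at least 5 FPKM, and genes varied independently of each other. These shares therefore do not carry over to genes of a few FPKM or to genes that vary together.

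Alternatives fixed beforehand were quantile normalization, median scaling, array weights, no filter, a filter at 5 FPKM, a pseudocount of 0.1, moderation that was not robust, the replicate number as a block, and leaving out each library. For the lists they also included an estimated correlation and fry. Added after the data were seen were Xist or the mean of the muscle list as a covariate, leaving out small RNA genes, and leaving out the 2 controls that express Xist. The lists of genes that decline after birth, of sterol synthesis and of muscle isoforms were also made after the data were seen.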

Results

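The mandibular condylar cartilage is the growth cartilage that covers the condyle of the lower jaw at the temporomandibular joint. RNA was sequenced from condylar cartilage of control mice, whose label fl/fl is the usual notation for a floxed gene. It was compared with cartilage of mutant mice in which the gene for Indian hedgehog (Ihh) had been deleted in craniofacial neural crest cells. Each group had 3 libraries. The labels give neither the age nor the sex of the mice. They do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Sex-linked genes, described below, show that control 3 differed in sex from controls 1 and 2 and so came from other animals. Values were FPKM (fragments scaled to transcript length and to library depth) for 24346 genes, of which 17761 to 18359 per library reached 1 FPKM. The number of fragments per library was not known, but the spacing of low values gave scaling totals relative to control 1 of 0.993 for control 2, 1.33 for control 3, 0.998 for mutant 1, 1.201 for mutant 2 and 1.05 for mutant 3. Olfactory receptor genes, which are largely silent outside the nose, served as a measure of background: 39.2% to 42.8% of 1120 such genes reached 1 FPKM, and their 90th percentile was 6.49 to 8.69 FPKM. Values of a few FPKM therefore lay in the range of genes taken to be silent.

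The comparison of mutant with control cartilage asked which transcripts differed after deletion of Ihh from the craniofacial neural crest. Ihh, the hedgehog ligand of prehypertrophic chondrocytes, measured 3.73, 2.51 and 3.74 FPKM in controls 1, 2 and 3 and 2.18, 2.33 and 2.66 FPKM in mutants 1, 2 and 3, a difference that did not pass the test. Gli1, a transcription factor and direct target of hedgehog signalling, fell from 8.70 ± 1.39 FPKM in controls to 0.516 ± 0.323 FPKM in mutants (mean ± SD, n = 3 per group), where the mutant values lay in the range of the silent genes. Of 21 cartilage matrix genes 5 fell, among them Hapln1, which stabilises aggrecan on hyaluronan (from 65.3 ± 3.16 to 15.5 ± 2.46 FPKM), and of 32 cell cycle genes 4 fell, among them Cdk1, the mitotic kinase (from 33.5 ± 3.16 to 13.3 ± 3.79 FPKM). Of 24 skeletal muscle genes 9 rose, among them Myh1, a fast myosin heavy chain (from 43.8 ± 11.9 to 314 ± 145 FPKM), and of 18 endothelial genes 3 rose, among them the adhesion gene Pecam1 (from 14.1 ± 6.83 to 48.2 ± 1.92 FPKM). Each of these 4 lists was called by camera with its preset correlation and not with an estimated correlation (adjusted p of 0.343 to 0.346).

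Among the 18715 genes with at least 1 FPKM in at least 3 libraries, 232 differed between the groups at a Benjamini-Hochberg adjusted p below 0.05 (limma), 145 of them higher and 87 lower in mutants. In all 232, the 3 mutant values lay beyond the 3 control values. Separation of this kind was seen in 19.2% of all genes tested, where chance gives 10%. At an unadjusted p below 0.05 there were 2630 genes, where chance gives 936. The first principal component carried 31.4% of the variance and placed the controls between -56.7 and -26.0 and the mutants between 21.1 and 50.7. The X-inactivation transcript Xist measured 29.5 and 29.2 FPKM in controls 1 and 2, 0.608 FPKM in control 3 and 0.577 to 0.984 FPKM in mutants. The Y-linked gene Eif2s3y measured 0.89, 0 and 42.1 FPKM in controls 1, 2 and 3 and 38.4 to 47.4 FPKM in mutants, so that the sexes were unequal between the groups. In settings chosen after the data were seen, 5 genes passed when controls 1 and 2 were left out, with the remaining control assumed to vary as the mutants did. With Xist as a covariate 2 passed, and 3 with the mean of the skeletal muscle list as a covariate. The count also depended on single libraries, with 13 genes passing without control 1, 20 without control 2, 19 without mutant 1, 57 without mutant 2 and 414 without mutant 3. Without control 3 it was 199, with 38 of those genes lower. The genes passing without control 1, control 2 and control 3 included 10, 17 and 125 of the 232. Those passing without mutant 1, mutant 2 and mutant 3 included 17, 47 and 199 of the 232. The count was 133 without a filter on low values, 440 with a filter at 5 FPKM and 411 after quantile normalization. The 232 genes kept their direction in every one of these fits that tested them. Of the 58 called genes that are named, 51 lost their call without control 1, 49 without control 2, 21 without control 3, 48 without mutant 1, 32 without mutant 2 and 11 without mutant 3. With the Xist covariate, the muscle covariate or controls 1 and 2 left out, 56 lost it, leaving Mir6385 and Snora68.

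**Figure D1:**
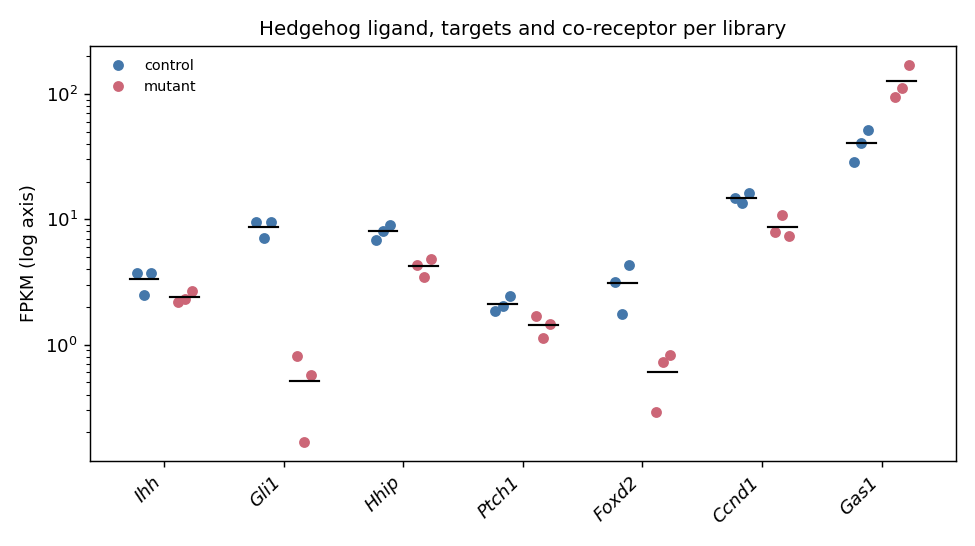
FPKM on a log axis for the hedgehog ligand Ihh, 5 hedgehog targets and the co-receptor Gas1, with 1 point per library (blue, control; red, mutant) and a bar at each group mean. The mutant Gli1 values lie between 0.168 and 0.807 FPKM, all below the control values of 7.10 to 9.53 FPKM, while the Ihh values of the groups overlap.

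Ihh lies on chromosome 1 from 74945315 to 74951672 on the minus strand (mm10). Its log2 fold change, on the scale of log2(FPKM + 1) used throughout, was -0.34 ± 0.30 (SE; limma adjusted p = 0.724, in a range from 0.678 to 0.899 over the settings tried). That scale understates the changes of genes at low values such as Ihh. The spacing of the values gave whole fragments of 12, 8 and 16 in controls 1, 2 and 3 and 7, 9 and 9 in mutants 1, 2 and 3, as the smallest numbers that fit all 6 values within 0.1 of a fragment. After scaling, the mutant to control ratio was 0.71 with an exact 95% interval from 0.408 to 1.215, which covers counting error only. If these smallest numbers hold, counting error alone excluded neither an unchanged level nor a fall to 0.408 of the control level. In the 6 libraries Ihh stood between the 67.9th and 81.9th percentiles of the olfactory receptor genes. The labels do not say which part of Ihh was deleted, so reads from the remainder of the gene were not separated from reads of the intact gene.

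Of 11 tested genes of the hedgehog response, Gli1 fell over all genes tested (log2 fold change -2.69 ± 0.32, limma adjusted p = 0.0152). Gli1, Foxd2, Ccnd1 and Hhip, 4 genes, fell when adjusted over the list alone. Foxd2, a forkhead factor of facial mesenchyme, measured 3.08 ± 1.30 FPKM in controls and 0.610 ± 0.283 FPKM in mutants (adjusted p over all genes = 0.154). As the smallest whole numbers that fit, these values corresponded to 37 fragments in controls and 7 in mutants. The scaled ratio was 0.193 with an exact 95% interval from 0.073 to 0.439. Hhip, a hedgehog-binding antagonist that is itself a target, measured 8.01 ± 1.13 and 4.21 ± 0.69 FPKM, and the cyclin Ccnd1 14.8 ± 1.35 and 8.71 ± 1.85 FPKM. The receptor and target Ptch1 measured 2.11 ± 0.28 and 1.43 ± 0.29 FPKM, with 42 and 27 fragments and a ratio of 0.657 (exact 95% interval from 0.389 to 1.091). Pthlh, which encodes the parathyroid hormone-related protein that acts in a loop with Ihh in growth plates, measured 16.6 ± 9.06 and 15.5 ± 3.31 FPKM. The log2 fold changes of Pthlh, Foxf1, Foxf2, Foxl1 and Osr2 lay between -0.42 and 0.36, with adjusted p from 0.741 to 0.997, and Foxd1, at 0 to 0.879 FPKM, was not tested. As a list these genes were lower than other genes (camera adjusted p = 0.0014), with an adjusted p of 0.346 under an estimated correlation. The call of Gli1 was lost without control 1 (adjusted p = 0.0709) or control 2 (adjusted p = 0.0524), in a range from 0.00774 to 0.675 over all settings tried. Exons of Gli1, Hhip and Ccnd1 overlap genes on the opposite strand, which these libraries do not separate. Below the 90th percentile of the olfactory receptor genes lay Foxd2 and Ptch1 in every library, Hhip in all mutants and controls 1 and 2, Gli1 in all mutants and control 2, and Ccnd1 in mutants 1 and 3.

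Of 20 tested genes of the hedgehog machinery, 1 rose, the co-receptor Gas1, from 40.2 ± 11.4 to 125.6 ± 40.2 FPKM (log2 fold change 1.61 ± 0.28, limma adjusted p = 0.0371). Gas1 rose and 2 genes fell when adjusted over the list alone, the glypican Gpc3 (109 ± 22.0 to 53.1 ± 19.7 FPKM) and the ciliary gene Evc (7.32 ± 0.56 to 3.61 ± 0.43 FPKM). Smo, the transducer that Ptch1 restrains, measured 22.3 ± 6.15 and 13.3 ± 1.25 FPKM (adjusted p = 0.244). The list as a whole did not pass (camera adjusted p = 0.127). Gas1 was not called without control 1, control 2, mutant 1 or mutant 2, with adjusted p of 0.117, 0.109, 0.0883 and 0.0976 in a range from 0.0184 to 0.675, nor without a filter on low values.

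Of 21 tested cartilage matrix genes, 5 fell and none rose over all genes tested. They were Hapln1 (log2 fold change -2.02 ± 0.19, limma adjusted p = 0.00943), the large proteoglycan Acan (29.1 ± 3.38 to 11.7 ± 2.65 FPKM) and 3 collagen genes. These were the type IX collagen genes Col9a1 (30.3 ± 9.52 to 8.53 ± 3.75 FPKM) and Col9a2 (25.4 ± 8.41 to 7.21 ± 2.08 FPKM), and Col11a1 (70.7 ± 6.72 to 27.7 ± 11.4 FPKM), the last chosen after its values were seen. Adjusted over the list alone, 10 fell and 2 rose. Among the 10 was Col2a1, the main collagen of cartilage, which was also chosen after its values were seen, at 118 ± 36.8 FPKM in controls and 51.0 ± 18.8 FPKM in mutants (adjusted p over all genes = 0.107). The 2 that rose over the list alone, again chosen after their values were seen, were the cell-binding matrix gene Chad (9.74 ± 2.90 to 55.0 ± 52.4 FPKM) and the pentameric matrix gene Comp (14.9 ± 6.91 to 50.8 ± 36.4 FPKM). The list was lower as a set (median log2 fold change -0.65, camera adjusted p = 1.33e-04), with an adjusted p of 0.343 under an estimated correlation. The count of 5 became 1 without control 1, control 2, control 3 or mutant 1, and 2 without mutant 2 or mutant 3. Beside these genes, the mean of the skeletal muscle list was 5.60 to 6.71 log2 units in controls and 7.29 to 8.0 in mutants.

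Of 17 tested genes of hypertrophic chondrocytes, 1 fell, the channel gene Panx3, from 152 ± 26.7 to 39.0 ± 8.72 FPKM (log2 fold change -1.95 ± 0.22, limma adjusted p = 0.0125). Panx3 and Col10a1 fell, 2 genes, when adjusted over the list alone. Col10a1, the collagen of the hypertrophic zone, measured 78.1, 75.0 and 14.7 FPKM in controls 1, 2 and 3 and 5.19 to 10.97 FPKM in mutants (adjusted p over all genes = 0.108). Its log2 fold change of -2.28 became -3.05 without control 3 (adjusted p = 0.0137), the only control without Xist. It became -0.79 with the Xist covariate (adjusted p = 0.541), -0.74 with controls 1 and 2 left out (adjusted p = 0.708) and -0.99 with the muscle covariate (adjusted p = 0.917). Panx3 was not called without control 1, control 2 or mutant 1. The list did not pass (camera adjusted p = 0.112).

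**Figure D2:**
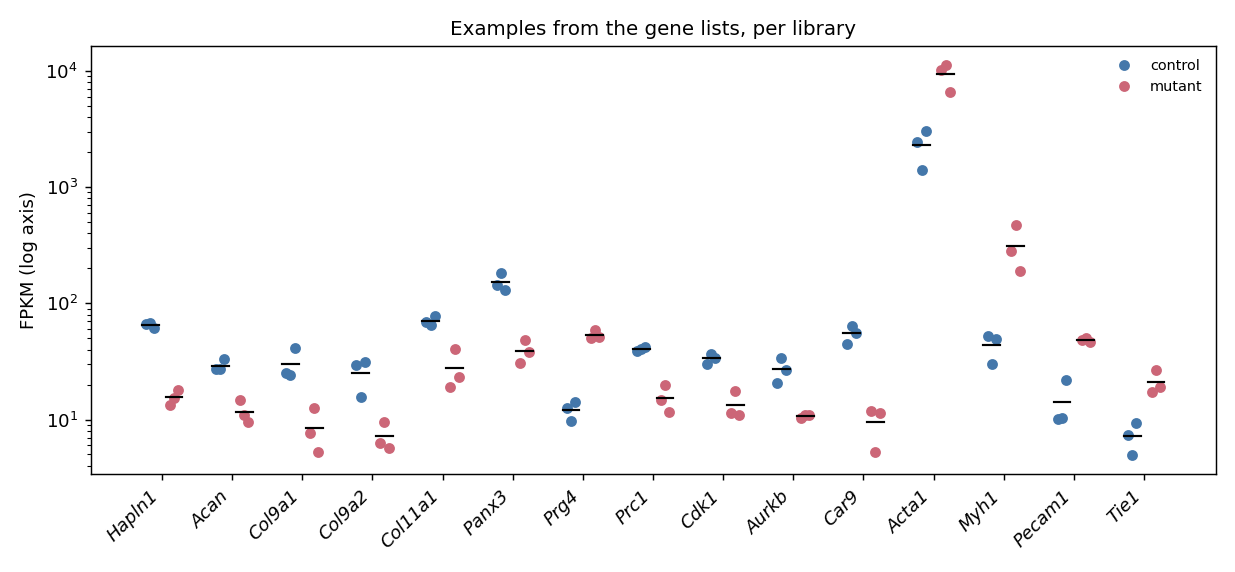
FPKM on a log axis for 15 genes of the fixed lists, with 1 point per library (blue, control; red, mutant) and a bar at each group mean. The control and mutant points of each gene do not overlap: the mutant points are the higher ones for Prg4, Acta1, Myh1, Pecam1 and Tie1 and the lower ones for the other 10 genes.

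All 32 cell cycle genes tested had a negative log2 fold change, with a median of -0.79. Over all genes tested 4 fell, namely the spindle midzone gene Prc1 (40.5 ± 1.75 to 15.4 ± 4.23 FPKM, log2 fold change -1.37 ± 0.22, limma adjusted p = 0.0301), Cdk1, the mitotic kinase Aurkb (27.1 ± 6.48 to 10.7 ± 0.33 FPKM) and the kinesin Kif20a (12.2 ± 0.51 to 3.90 ± 1.58 FPKM). In all, 23 fell when adjusted over the list alone. The list was lower as a set (camera adjusted p = 7.67e-17), with an adjusted p of 0.346 under an estimated correlation. The count of 4 became 0 without control 1, control 2, control 3 or mutant 1, and 1 without mutant 3. The list's mean was 4.52, 4.66 and 4.60 log2 units in controls 1, 2 and 3, of which controls 1 and 2 expressed Xist, and 3.68, 4.09 and 3.47 in mutants 1, 2 and 3, in which the muscle list was higher.

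Genes of the fibrous and progenitor layer changed in both directions, with 1 of 26 rising and 2 falling. Prg4, which encodes the joint lubricant lubricin, rose from 12.1 ± 2.21 to 53.6 ± 4.86 FPKM (log2 fold change 2.07 ± 0.20, limma adjusted p = 0.00943). The matricellular gene Postn fell from 960 ± 118 to 266 ± 102 FPKM and Tnc from 160 ± 22.3 to 63.9 ± 11.6 FPKM. Adjusted over the list alone, 2 rose and 4 fell, the additional members being Cd34 (84.2 ± 16.6 to 139 ± 27.8 FPKM), Tnn (118 ± 10.3 to 46.4 ± 30.0 FPKM) and Aspn (497 ± 71.5 to 237 ± 107 FPKM), of which Cd34 and Aspn were chosen after their values were seen. The list did not pass (camera adjusted p = 0.615). Of 15 tested genes of the TGF-beta response, 3 fell, Postn, Tgfbi (261 ± 40.3 to 80.2 ± 24.6 FPKM) and the smooth muscle actin Acta2 (123 ± 4.67 to 58.8 ± 6.63 FPKM). With these, Loxl2 fell when adjusted over the list alone (83.7 ± 4.38 to 54.7 ± 2.04 FPKM), and the list had a camera adjusted p of 0.0817. Of 18 tested osteoblast and osteocyte genes, 1 fell, Cthrc1, a secreted gene of collagen-producing cells, from 523 ± 48.6 to 118 ± 42.2 FPKM, over all genes and over the list alone. That list's median log2 fold change was 0.10 while its mean was -0.04 and its test pointed lower (camera adjusted p = 0.843). Prg4 stayed called whichever library was left out, whereas Postn, Tnc and Cthrc1 were not called without control 1, control 2 or mutant 1, and neither Tgfbi nor Acta2 was called without those or mutant 2. Acta2 was also not called without control 3.

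Of 27 tested genes of hypoxia and glycolysis, 5 fell. Among them were the prolyl hydroxylases P4ha2 (156 ± 25.1 to 48.9 ± 2.64 FPKM, log2 fold change -1.64 ± 0.18, limma adjusted p = 0.0125) and P4ha1 (67.1 ± 2.55 to 28.2 ± 4.42 FPKM), which modify collagen. The others were the glycolytic enzymes Pgam1 (366 ± 29.5 to 143 ± 6.65 FPKM) and Eno1 (328 ± 45.8 to 165 ± 22.9 FPKM) and the carbonic anhydrase Car9 (55.0 ± 9.77 to 9.51 ± 3.67 FPKM). Eno1 was chosen after its values were seen. Adjusted over the list alone, 10 fell and 2 rose, the aldolase Aldoa, which muscle expresses strongly (826 ± 215 to 1734 ± 420 FPKM), and Adm (1.58 ± 1.81 to 7.37 ± 1.27 FPKM), both chosen after their values were seen. The list was lower as a set (camera adjusted p = 3.37e-05), with an adjusted p of 0.346 under an estimated correlation. Of 25 tested genes of endoplasmic reticulum stress, 3 fell, all of them folding factors of secreted proteins: Hsp90b1 (235 ± 24.3 to 98.7 ± 6.75 FPKM), Manf (45.4 ± 5.29 to 18.8 ± 4.10 FPKM) and Pdia4 (102 ± 10.3 to 51.9 ± 1.5 FPKM). Adjusted over that list alone, 9 fell and 1 rose, the stress transcription factor Ddit3 (19.5 ± 3.60 to 31.0 ± 5.99 FPKM), chosen after its values were seen. The list was lower as a set (camera adjusted p = 2.78e-04), with an adjusted p of 0.411 under an estimated correlation. Of the 5 and 3 calls, 1 and 0 were left without control 1, 0 and 0 without control 2, 1 and 0 without mutant 1 and 3 and 0 without mutant 2. Without control 3, 1 of the 3 was left. As for the cartilage and cell cycle lists, the skeletal muscle list and Xist differed between the same groups.

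Skeletal muscle genes rose in 9 of 24 tested and in 19 of 24 adjusted over the list alone. Examples were Myh1 (log2 fold change 2.75 ± 0.34, limma adjusted p = 0.0157), the calcium pump Atp2a1 (141 ± 56.7 to 894 ± 388 FPKM), the sarcomere gene Myoz1 (93.2 ± 29.2 to 429 ± 143 FPKM) and the intermediate filament gene Des (52.8 ± 13.6 to 255 ± 76.6 FPKM), which is also on the pericyte list. Acta1, the most abundant actin of muscle and chosen after its values were seen, rose from 2296 ± 832 to 9327 ± 2404 FPKM. The list was higher as a set (median log2 fold change 1.55, camera adjusted p = 3.80e-17), with an adjusted p of 0.346 under an estimated correlation. The count of 9 became 0 without control 1, control 2 or mutant 1 and 1 without mutant 2, and it was 5 without a filter on low values. All 18 endothelial genes had a positive log2 fold change, and 13 rose when adjusted over the list alone. Over all genes 3 rose, Pecam1, the tight junction gene Cldn5 (9.38 ± 2.76 to 25.3 ± 5.16 FPKM) and the receptor Tie1 (7.20 ± 2.15 to 21.05 ± 5.08 FPKM). The endothelial list was higher as a set (median log2 fold change 1.003, camera adjusted p = 2.96e-12), with an adjusted p of 0.343 under an estimated correlation. The count of 3 became 0 without control 1, control 2, mutant 1 or mutant 2 and 6 without control 3.

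Among markers of other cell types, fewer genes were called. Of 13 erythroid genes 1 rose, the carbonic anhydrase Car1 (2.97 ± 3.60 to 29.7 ± 14.7 FPKM). Of 14 adipocyte genes 1 rose, the lipid droplet gene Plin4, joined over the list alone by Fabp4, Lpl and Car3. Both lists were higher as sets, with camera adjusted p of 0.0039 and 0.0233, and adjusted p of 0.505 under an estimated correlation. The list of neutrophils and marrow was higher (camera adjusted p = 0.0014, and 0.505 under an estimated correlation) with none of its 13 genes called, and the serine protease Prtn3 rose over the list alone. The erythroid call was lost without control 2 (adjusted p = 0.108) or mutant 2 (0.0891), the neutrophil call without mutant 2 (0.0588) and the adipocyte call without control 1 (0.178), control 2 (0.0727) or mutant 1 (0.138). The adipocyte call was also lost with the Xist covariate (adjusted p = 0.847), with controls 1 and 2 left out (0.955) and with a filter at 5 FPKM (0.258). Its mean was 2.48 and 2.64 log2 units in controls 1 and 2, which expressed Xist, 3.61 in control 3 and 3.23 to 3.95 in mutants. The dissection stress list, of immediate early and heat shock genes, was higher (camera adjusted p = 0.0031, and 0.411 under an estimated correlation) with none of 21 genes called. Adjusted over that list alone 5 rose, Dusp1, Ier2, Hspb1, Zfp36 and, chosen after its values were seen, Socs3, and the call of the list was lost without mutant 2 (adjusted p = 0.0983). With the muscle covariate the dissection stress list was not called (adjusted p = 0.336), and the neutrophil, erythroid and adipocyte lists turned to lower without passing (adjusted p of 0.828, 0.162 and 0.419). Of 12 tested pericyte and smooth muscle genes, Des rose and Acta2 fell, with Mcam and Rgs5 rising and Cspg4 falling over the list alone, Rgs5 being chosen after its values were seen (camera adjusted p = 0.112). Of 16 tested macrophage genes none was called and Tyrobp rose over the list alone (48.5 ± 11.8 to 115 ± 44.6 FPKM, camera adjusted p = 0.121).

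**Figure D3:**
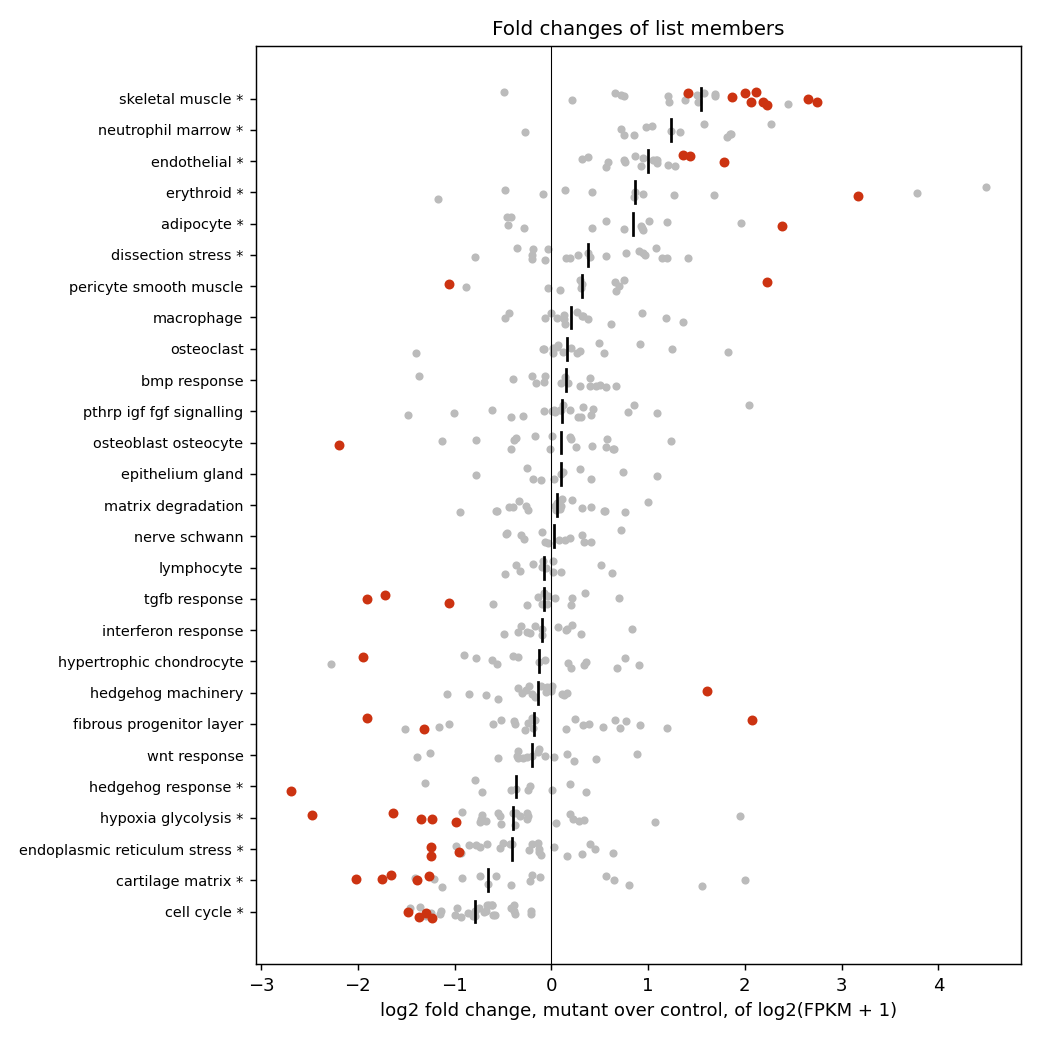
Log2 fold changes, mutant over control, of the tested members of the 27 gene lists, with 1 point per gene, red points for genes past the threshold and a black bar at each median. An asterisk marks the 11 lists called by camera with its preset correlation, from the skeletal muscle list (median 1.55) to the cell cycle list (median -0.79).

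Of 22 tested genes of PTHrP, IGF and FGF signalling, none was called over all genes. Adjusted over the list alone, the binding proteins Igfbp2 (3.01 ± 3.06 to 13.2 ± 3.46 FPKM), Igfbp3 and Igfbp7 rose, and the receptors Fgfr2 (53.1 ± 14.2 to 18.7 ± 7.02 FPKM) and Fgfr3 (22.1 ± 7.12 to 10.4 ± 2.97 FPKM) fell, Fgfr3 being chosen after its values were seen. Fgfr2 missed the threshold over all genes in limma (adjusted p = 0.0531), in a range from 0.0236 to 0.675 over the settings tried, and the list did not pass (camera adjusted p = 0.437). Of 21 tested genes of matrix degradation, the cathepsin Ctsl rose over the list alone (46.2 ± 14.1 to 90.4 ± 5.04 FPKM, adjusted p over all genes = 0.0831), with a median of 0.06 for the list, a test that pointed lower and a camera adjusted p of 0.843. No gene was called, over all genes or over the list alone, among 17 Wnt response genes (camera adjusted p = 0.176), 16 BMP response genes (0.615), 16 osteoclast genes (0.268), 12 lymphocyte genes (0.803), 14 nerve and Schwann cell genes (0.817), 11 epithelium and gland genes (0.789) and 14 interferon response genes (0.817). Among these, the Wnt-responsive factor Tcf7 measured 14.1 ± 2.53 FPKM in controls and 5.62 ± 2.81 FPKM in mutants (limma adjusted p = 0.0991), and the ligand Bmp7 measured 4.65 ± 1.197 and 1.34 ± 1.19 FPKM (adjusted p = 0.166). The 13 mitochondrially encoded genes of the fixed list did not appear under those symbols and were not analysed here.

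The 10 largest called increases among genes above 5 FPKM on average included Plin5, a lipid droplet gene (1.38 ± 0.88 to 26.6 ± 12.8 FPKM), the muscle-specific ribosomal gene Rpl3l (6.77 ± 3.44 to 66.7 ± 32.1 FPKM), the muscle fructose bisphosphatase Fbp2 (21.2 ± 10.7 to 176 ± 71.1 FPKM) and Tmem182 (4.26 ± 2.08 to 39.1 ± 9.43 FPKM). The others were the sarcomere gene Tcap (65.9 ± 21.1 to 553 ± 275 FPKM), Pdk4, which restrains glucose oxidation (10.03 ± 0.35 to 103 ± 73.8 FPKM), the fatty acid binding gene Fabp3 (254 ± 76.1 to 2015 ± 888 FPKM), Car1 and Aldh1a1, which makes retinoic acid (5.99 ± 1.87 to 46.8 ± 15.6 FPKM). Their log2 fold changes ran from 2.75 to 3.498. The tenth, the microRNA gene Mir6385, was listed at 0 in the 3 controls and at 673, 1118 and 1274 FPKM in mutants 1, 2 and 3. It lies within Pml, on the opposite strand, and overlaps an exon of Pml. Apart from Mir6385, which stayed called, all of these calls were lost without mutant 1. All but that of Tmem182 were lost without control 1, those of Car1, Rpl3l, Fbp2, Tcap, Pdk4 and Fabp3 without control 2, those of Car1, Fbp2, Tcap, Pdk4 and Fabp3 without mutant 2 and those of Car1 and Pdk4 without control 3.

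The 10 largest called decreases among genes above 5 FPKM on average included Hapln1, Cthrc1 and Car9. Among the others, C1qtnf3, a secreted protein of cartilage, fell from 580 ± 111 to 116 ± 43.8 FPKM (log2 fold change -2.36 ± 0.28, limma adjusted p = 0.0152), the serine protease-like gene Prss35 from 73.7 ± 10.1 to 17.7 ± 10.1 FPKM and Zfp185 from 23.8 ± 2.65 to 4.22 ± 1.28 FPKM. The retinoic acid binding gene Crabp1 fell from 72.9 ± 42.1 to 14.1 ± 4.98 FPKM and Aldh1a3, like Aldh1a1 a maker of retinoic acid, from 17.8 ± 4.56 to 3.53 ± 0.57 FPKM, so that Aldh1a1 and Aldh1a3 changed in opposite directions. Morn2 fell from 13.2 ± 0.91 to 0.880 ± 1.52 FPKM, with exons that overlap Dhx57 on the opposite strand. Snora68, a small nucleolar RNA gene, was listed at 0 in the 3 mutants and measured 2904 ± 1594 FPKM in controls. FPKM divides by transcript length and so magnifies a few fragments at RNAs as short as Mir6385 and Snora68. Hapln1 and Snora68 stayed called whichever library was left out, and the other 8 calls were lost without control 1. Those of C1qtnf3, Car9, Cthrc1, Prss35, Crabp1 and Morn2 were lost without control 2, those of Prss35, Crabp1 and Morn2 without control 3, those of Cthrc1, Prss35, Crabp1, Morn2 and Aldh1a3 without mutant 1 and that of Crabp1 without mutant 2.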

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

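The genes counted as changed, higher and lower (232, 145 and 87) stayed within 1.5 times of these counts under median scaling, array weights, a pseudocount of 0.1, moderation that was not robust and without small RNA genes. They were 411, 239 and 172 with quantile normalization, 440, 278 and 162 with a filter at 5 FPKM, which tested fewer genes, and 133, 80 and 53 with no filter, which tested more. Leaving out 1 library gave 13 to 414 changed, 6 to 315 higher and 5 to 99 lower genes. With the replicate number as a replicate block they were 2, 1 and 1. Deviations of libraries with the same number correlated at 0.0063, -0.016 and -0.0091, and not every library correlated best with its own number. Pairing by number was thus not seen, though correlations this small cannot exclude it. Settings chosen after seeing the data gave 2, 1 and 1 genes with the Xist covariate, 3, 1 and 2 with the muscle covariate and 5, 4 and 1 with the Xist-expressing controls left out, where the lone control was assumed to vary like the mutants. Xist and the muscle mean both differ between the groups, so by construction each covariate takes up part of the group difference. All 232 genes kept their direction in every setting that tested them. Ihh stayed uncalled in 17 settings, its log2 fold change lying between -0.65 and -0.27, and was not tested with the filter at 5 FPKM.

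Of the 27 lists, 11 were called, against 0 with an estimated correlation, 4 with fry, which tests a list against no change instead of against other genes (endothelial, cartilage matrix, hypoxia and glycolysis, cell cycle), and 6 with the muscle covariate, which kept those 4, endoplasmic reticulum stress and the hedgehog response. Leaving out 1 library gave 9 to 14. With the muscle covariate, the direction reversed for neutrophils and marrow (adjusted p = 0.828), erythroid genes (0.162) and adipocytes (0.419), and for Aldoa (log2 fold change -0.10), Hspb1 (-0.39), Lpl (-0.14), Fabp4 (-0.90), Tnnt1 (-0.48) and S100a9 (-0.0085).

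Other reversals were of uncalled hedgehog response genes. Pthlh took -0.0048 with median scaling, -0.74 with the Xist covariate, -0.39 with the muscle covariate and -0.77 with the Xist-expressing controls left out. Foxf2 took -0.57, -0.16 and -0.54 in the last 3 settings and Osr2 -0.64, -2.22 and -0.69, and Foxl1 took 0.056 with the muscle covariate. Leaving out 1 library gave -0.30 to 0.40 for Pthlh and -0.32 to 0.64 for Osr2. Apart from the numbers of genes tested, the cause was not tested. The alternatives DESeq2, DESeq2 size factors, upper-quartile scaling and limma-voom were not run, since the values are not counts. Depth may limit genes of a few FPKM, as the smallest whole numbers that fit gave Ihh 36 fragments in controls and 25 in mutants.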

Other observations

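Genes of sterol synthesis, a list made after the data were seen, were lower in mutants. Of 23 tested, 5 fell: Fdps (161 ± 40.6 to 44.4 ± 4.64 FPKM, log2 fold change -1.81 ± 0.23, limma adjusted p = 0.0157), which makes farnesyl diphosphate, and the sterol enzymes Sqle (35.3 ± 7.92 to 9.65 ± 4.95 FPKM), Msmo1 (42.4 ± 10.4 to 10.8 ± 3.76 FPKM), Cyp51 (21.7 ± 2.80 to 7.28 ± 2.54 FPKM) and Hmgcs1 (44.4 ± 4.10 to 17.4 ± 3.03 FPKM). The log2 fold change was negative in 21 of 23, with a median of -0.98. Of these 5 calls, 1 was left without control 1, control 3 or mutant 2, 0 without control 2, 2 without mutant 1 and 4 without mutant 3, and 0 with the Xist covariate, the muscle covariate or controls 1 and 2 left out, though all 5 genes stayed lower in each. The skeletal muscle list and Xist differed between the same groups. The list had been prompted by Fdps, Sqle, Msmo1 and Cyp51, so the test of the other 19 members was written before its result was seen. Their median was -0.894, with 17 of 19 lower, a camera p of 1.24e-10 with the preset correlation (a test across genes, not exact) and 0.0085 with an estimated correlation. Neither p was adjusted over lists, unlike the camera values given for the fixed lists, so they cannot be compared directly. Hmgcs1, itself called, was among the 19. The set test was not repeated with a library left out or with a covariate. Most of the other members were thus lower too. Members of a pathway may vary together with the genes that prompted the list, so the test is not independent evidence of a decrease as a set.

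Of the tests of the lower cartilage matrix and cell cycle lists, that of developmental stage was written before its result was seen, and those of muscle and sex after. More muscle in the mutant dissections could lower all other genes alike, but 44 osteoblast and fibrous layer genes had a median log2 fold change of -0.09 against -0.75 for 53 cartilage and cell cycle genes, a difference of 0.658 (permutation p = 1e-05, the smallest possible). This permutation p is too small, since it treats genes as independent. The cell cycle list, for example, had an estimated correlation of 0.312. The difference of 0.658 is below the SD of the 44 genes (0.84), of which 21 were higher, and the lower lists were chosen for being lower. With the muscle covariate both lists stayed called by camera with its preset correlation (adjusted p = 0.031 for cartilage matrix and 5.61e-09 for cell cycle). The muscle list did not (camera adjusted p = 0.656), but this follows by construction, since the covariate is that list's own mean. The mean of the cartilage list moved from -0.48 ± 0.13 (SE) to -0.41 ± 0.32 and that of the cell cycle list from -0.84 ± 0.19 to -1.11 ± 0.44, with wider errors between libraries, so dilution stays open. Across these genes the control without Xist differed from the Xist-expressing controls by a median of 0.0546, against -0.715 for mutants, but with 1 such control the part of sex stays open. A difference in stage might also act, and 20 genes that decline after birth had a median of -0.128 (p = 0.244, permutation against random lists), with 1 called, Mest (346 ± 118 to 134 ± 11.7 FPKM, adjusted p = 0.0413), and because 12 were lower and 8 higher, this median near 0 decides nothing.

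The test of the higher skeletal muscle list was chosen only after the result was seen. Its most abundant marker, Acta1, measured 2296 ± 832 FPKM in controls and 9327 ± 2404 FPKM in mutants, and 1 of its genes, Des, is also on the pericyte list. More muscle of the same kind would raise its isoforms alike, but 17 adult fast genes had a median log2 fold change of 1.69 and 12 developmental and slow genes of -0.32, with 5 of the 12 positive, among them slow Tnnt1 (23.7 ± 16.3 to 65.2 ± 26.8 FPKM, log2 fold change 1.58), which rose over the muscle list alone. The other 7 were negative, among them slow Myl2, Tnnc1 and Tnni1 with log2 fold changes of -2.67, -2.64 and -1.11. Developmental genes also went both ways, with 0.75 for Myh8 and -0.49 for Myh3. Over all genes tested, 0 of the 12 rose and 0 fell. The difference of 2.01 exceeds the SD of the 12 genes (1.29) but cannot decide the question. Most of the fast genes were members of the muscle list, whose rise was already known. Among the 12, Chrng, Myh7 and Tnnt2 had means of 1.76, 2.27 and 5.44 FPKM in controls, in the range of genes taken to be silent. The permutation p of 4e-05 is too small, since it treats genes as independent. The muscle list had an estimated correlation of 0.616. Tnnt1, Myl2, Tnnc1, Tnni1, Myh8 and Myh3 were chosen after their values were seen. These isoform lists were widened once after a first result of the same direction, because they had left out known isoforms.

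Of the tests of Ihh and of the count of called genes, those of background and mislabelling were chosen only after the result was seen, and that of other groupings before. Ihh stood at most at percentile 81.9 of the olfactory receptor genes in any library, so its values may be background, which fits a test that could not call it lower. The highest mutant Gli1 value was 0.114 of the lowest control value, so no mutant library had a Gli1 value near the control range. Gli1 had already been called lower with full separation, so this was no independent test of mislabelling. Of 10 splits of the libraries into 3 and 3, only 1, the real one, gave as many as 232 genes and the highest other gave 6, but 10 splits are too few for a share under 0.05.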
